A study of Mus musculus with 9 samples.

How the data were processed

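Ribosome-associated RNA of mPFC neurons was measured by RNA sequencing in 9 mouse libraries: 3 of GFP control mice in sleep, 3 of GFP control mice in enforced wake and 3 of mice with GFP-Fxr1 overexpression in enforced wake. RNA was pulled down by RiboTag immunoprecipitation and libraries were made with a stranded total RNA kit, per the labels' protocols. Total RNA libraries hold non-coding RNA besides messenger RNA, and no step of the pull-down reports the share of RNA from other cells, so marker lists of other cell types were measured as well.

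The authors deposited 2 tables of transcript values, 1 for sleep and enforced wake and 1 for enforced wake with and without Fxr1. Each holds FPKM per transcript and library as estimated by the authors, per the file headers, that is fragments per kilobase of transcript, scaled by the number of mapped fragments. Each table also holds the authors' fold change and their p-value and q-value for each transcript, per the file headers. Per the submitters' processing notes the tools were HISAT2 2.1.0, SAMtools 1.9 and StringTie 1.3.4d with the genome build GRCm38; the tool behind the fold changes, p-values and q-values is not given in the sources used here. Each table lists 115220 transcripts, and the enforced wake control values were identical in both tables, so the 9 libraries could be set side by side. The authors' fold was compared with the FPKM columns: it was sleep over enforced wake in the first table and Fxr1 over control in the second, so the first table has the opposite direction to that used here.

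FPKM are not counts, so no count model was used. FPKM divide each library by its own total, which makes every value relative to the rest of the library: a rise of abundant RNAs lowers all others. A transcript estimate can also switch between transcripts of a gene that share exons, so genes were tested as the sum of the FPKM of their transcripts by gene symbol, and single transcripts separately. The tables give no read totals. Depth was estimated from the smallest steps of FPKM times transcript length in genes with 1 transcript, which gave 2.99e7 to 3.74e7 fragments per library. The sum of FPKM per library was 309832 to 358936.

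Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend), 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Genes or transcripts with a mean FPKM of at least 0.5 over the libraries compared were kept. A fold change is therefore a difference on the log2(FPKM + 1) scale, which understates the change of genes with low FPKM. Enforced wake against sleep and enforced wake with Fxr1 against enforced wake were each fitted on their own 6 libraries. Enforced wake with Fxr1 against sleep was fitted on all 9 libraries, which share 1 estimate of the spread. Directions are enforced wake minus sleep and Fxr1 minus control. With 3 against 3 libraries an exact permutation test of 1 gene cannot give a p below 0.1, so the adjusted p-values rest on limma's model over all genes.

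Before the data were examined, 25 gene lists with 494 genes were fixed: the fragile X family, immediate early genes, cold-inducible genes, chaperones and endoplasmic reticulum stress, ribosomal proteins, translation factors, GABA receptors, glutamate receptors, the postsynaptic density, presynaptic genes, Gsk3 and Akt signalling, the circadian clock, nuclear and mitochondrially encoded genes of oxidative phosphorylation, interferon response, and markers of excitatory, inhibitory and striatal neurons, astrocytes, oligodendrocytes and their precursors, microglia, endothelial and mural cells, blood, and meninges, choroid plexus and ependyma. Some genes stand in more than 1 list, such as Homer1. For each list the members passing over all genes and adjusted over the list alone were counted. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the 25 lists.

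The named genes follow a rule fixed before the data were examined. Fxr1, Fxr2 and Fmr1 were always taken. From each comparison came the 8 genes with the largest change in each direction among those passing with no overlap between the groups, leaving out gene models without a proper symbol. Up to 3 members of each list with the smallest p were added, and a gene taken for 1 comparison may be quoted in the others. Gene positions were taken from the GENCODE mouse annotation of GRCm38, which held 47310 of the 47729 gene identifiers of the tables (99.1%).

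After the data were seen, a correction was added: in each library, the deviation from the mean of all libraries was fitted with splines (5 degrees of freedom each) of the GC content and the log length of the longest transcript, over protein-coding genes with a mean FPKM of at least 1, and subtracted. It removes any real change that follows GC content too, so both values are given. GC values were present for 99.5% of the genes tested. Other added choices were the leave-out fits with that correction, the replicate block with it, the alternatives for the third comparison, and 6 further gene lists described in the closing part. Quantile normalization for the tests of the gene lists was also added. The alternatives fixed beforehand were a pseudocount of 0.1, no filter on low values, a mean FPKM of at least 2, size factors, quantile normalization, limma without trend but robust, the replicate number as a block, all 9 libraries in 1 fit, adjusted p thresholds of 0.1 and 0.01, a fold of at least 1.5, the authors' own p-values and q-values, and leaving out each replicate of each group in turn.

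The correlation of the fold changes of the 2 comparisons that share the enforced wake libraries was set beside 100 simulations of unchanged groups against the same control libraries. The fitting steps were tested on simulated data with 200 changed genes: for enforced wake against sleep 67% of genes changed by 1.5-fold and 86% of those changed by 2-fold were called, for enforced wake with Fxr1 against enforced wake 19% and 63%, and for enforced wake with Fxr1 against sleep 48% and 85%. False calls made up 5.56%, 4.40% and 8.33% of the calls. These simulations drew each gene independently and without a trend with GC content, so their rates leave out variation that genes share. The figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No sample was left out. Results that need genes withheld for evaluation are not reported here.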

Results

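Ribosome-associated RNA was measured in neurons of the medial prefrontal cortex (mPFC) of adult mice of the C57BL/6 strain. It was isolated by RiboTag immunoprecipitation, in which a tagged ribosomal protein is pulled down together with the RNA bound to ribosomes, and sequenced from stranded total RNA libraries. The 9 libraries fell into 3 groups of 3. In 2 of the groups green fluorescent protein (GFP) alone was overexpressed in the mPFC as a control, and the animals either slept or were kept awake (enforced wake). In the third group a fusion of GFP with Fxr1, an RNA-binding protein of the fragile X family, was overexpressed during enforced wake. The low values of the tables put the depth of the libraries at an estimated 2.99e7 to 3.74e7 fragments. Replicates correlated across genes with a Pearson r of 0.985 to 0.988 in sleep, 0.990 to 0.991 in enforced wake and 0.954 to 0.988 in enforced wake with Fxr1. Nothing in the labels says that the replicates came from separate animals, so the p-values below measure only the spread between these samples, which may be technical.

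Fxr1 library 1 stood apart from the other libraries. On the first principal component, which held 60.2% of the variance, it had a score of 57.7, against -27.7 to 10.8 in the other 8 libraries. The libraries also differed by the base composition of what was measured. Deviations from the mean of the 9 libraries rose with the GC content of the transcripts in the 3 enforced wake control libraries, with Spearman correlations across genes of 0.64, 0.69 and 0.73. They fell with GC content in the 3 Fxr1 libraries, with correlations of -0.80, -0.41 and -0.25. In the 3 sleep libraries the correlations were 0.25, -0.39 and 0.17, so the trend also differed between replicates of a group. Non-coding RNAs annotated as miscellaneous took 2.39% to 3.34% of total FPKM in sleep, 4.99% to 5.39% in enforced wake and 0.942% to 3.05% with Fxr1. Genes are not independent replicates, so these correlations are descriptions.

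**Figure D1:**
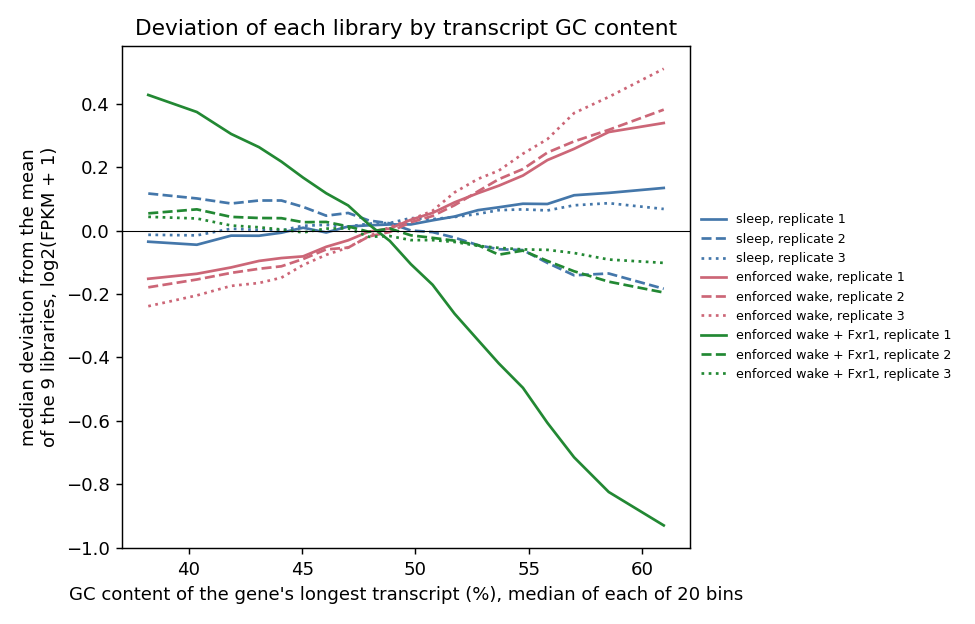
Median deviation of each of the 9 libraries from their mean, in log2(FPKM + 1), in 20 bins of genes ordered by the GC content of their longest transcript; each line is 1 library. The 3 enforced wake control lines climb with GC content and the 3 Fxr1 lines descend, Fxr1 replicate 1 the steepest, with a Spearman correlation of -0.80 across genes.

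The overexpressed gene was examined first. Fxr1 (ENSMUSG00000027680, GRCm38 chromosome 3, 34019943 to 34070322) had 32.5 ± 2.03 FPKM in sleep, 33.3 ± 1.97 in enforced wake and 76.9 ± 12.5 in enforced wake with Fxr1 (mean ± SD, n = 3 each). The 3 Fxr1 libraries had 91.1, 67.7 and 71.8 FPKM, all above the highest control library at 34.8. Fxr1 rose with overexpression by 1.17 on the log2(FPKM + 1) scale (SE 0.13, limma adjusted p = 0.0366) against enforced wake control. The change lay in several transcripts: ENSMUST00000197694 rose from 3.29 to 13.1 FPKM and ENSMUST00000001620 from 9.69 to 21.3. The most abundant transcript, ENSMUST00000200392, had 19.2 ± 1.56 and 39.1 ± 8.09 FPKM and did not pass (limma adjusted p = 0.0972). The log2 fold change of the gene lay between 1.05 and 1.26 with any 1 library left out. The limma adjusted p was above the threshold of 0.05 without enforced wake replicate 1, 2 or 3 (0.180, 0.192 and 0.224) and without Fxr1 replicate 2 or 3 (0.0690 and 0.0501).

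The comparison of enforced wake with sleep in GFP control mice asked which ribosome-associated RNAs differ between the states. Arc, a synaptic immediate early gene (ENSMUSG00000022602, chromosome 15, 74669083 to 74672570), rose from 10.9 ± 2.72 FPKM in sleep to 101.2 ± 5.01 in enforced wake (n = 3 each), by 3.13 on the log2(FPKM + 1) scale (SE 0.15, limma adjusted p = 0.000394). It led a group of activity-induced genes: of 33 measured immediate early genes 29 rose and 1 fell, with a median log2 fold change of 1.11, and the counts adjusted over the list alone were the same 29 and 1. Fos rose by 1.91 (SE 0.21), Fosb by 1.98 (SE 0.16), Junb by 1.9 (SE 0.17), Nr4a1 by 1.85 (SE 0.21), Egr1 by 1.27 (SE 0.07) and Inhba by 1.73 (SE 0.07), all at limma adjusted p of 0.00362 or less. The neuronal pentraxin Nptx2 rose by 1.81 (SE 0.15) and the small GTPase Rasd1 by 1.98 (SE 0.10). As a set the immediate early genes lay above other genes (camera adjusted p = 1.7e-17; adjusted p = 0.279 with an estimated correlation).

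Chaperones and folding enzymes of the endoplasmic reticulum also rose in enforced wake. In this list 23 of 29 genes rose and none fell, with the same counts adjusted over the list alone and a median log2 fold change of 0.59 (camera adjusted p = 1.9e-12; adjusted p = 0.279 with an estimated correlation). Pdia6, a disulfide isomerase, rose from 42.7 ± 2.12 to 88.0 ± 3.35 FPKM (log2 fold change 1.03, SE 0.06), Sdf2l1 by 1.63 (SE 0.10) and Creld2 by 1.16 (SE 0.06), at limma adjusted p of 0.000856 or less. Of 52 cytosolic ribosomal protein genes, 30 rose and none fell (33 and 0 adjusted over the list alone; median 0.29). With fry, which tests whether the genes of a list move on balance one way, the adjusted p was 0.000638 for the immediate early and chaperone lists and 0.00294 for the ribosomal protein list. Rplp1 rose by 0.84, Rps29 by 0.67 and Rpl13 by 0.40 (camera adjusted p of the list 1.4e-08; adjusted p = 0.279 with an estimated correlation). Both cold-inducible RNA-binding protein genes fell: Rbm3 (ENSMUSG00000031167, chromosome X, 8138975 to 8145880) from 86.9 ± 19.4 to 27.4 ± 4.37 FPKM, by 1.62 (SE 0.18, limma adjusted p = 0.00308), and Cirbp from 41.5 ± 3.45 to 20.9 ± 0.853 FPKM (log2 fold change -0.96, SE 0.07, limma adjusted p = 0.00131). The camera adjusted p of this list of 2 genes was 0.0115 (adjusted p = 0.279 with an estimated correlation).

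Synaptic genes moved in both directions. Of 15 genes of GABA receptors, the subunits of both receptor types and the anchoring protein gephyrin, 8 fell and none rose (11 and 0 adjusted over the list alone), with a median of -0.23 (camera adjusted p = 0.000302; adjusted p = 0.279 with an estimated correlation), and with the trend with GC content and length removed 4 fell (9 adjusted over the list alone; median -0.17). Among them Gabrb2 had a log2 fold change of -0.44 (SE 0.06), Gabra4 of -0.59 (SE 0.09) and Gabrg3 of -0.35 (SE 0.06). Of 31 postsynaptic density genes 11 rose and 2 fell (14 and 2 adjusted over the list alone; camera adjusted p = 0.00199; adjusted p = 0.531 with an estimated correlation). The scaffold gene Homer1 rose from 109 ± 7.41 to 190 ± 8.75 FPKM (log2 fold change 0.80, SE 0.07) and Baiap2 by 0.81. The Homer1 transcript ENSMUST00000080127 had a mean of 75.7 FPKM in sleep and 78.4 in enforced wake. By these estimates most of the Homer1 rise lay in other transcripts of the gene. With that trend removed, 5 of these 31 genes were higher and 3 lower, and the set call was lost (camera adjusted p = 0.119). Of 28 glutamate receptor genes 7 rose and 3 fell (10 and 4 adjusted over the list alone), Cacng8 by 0.91, while Grm3 and Gria4 had log2 fold changes of -0.59 and -0.40. With that trend removed none of the 28 was higher and 4 were lower, and Cacng8 no longer passed (limma adjusted p = 0.0795). Of 28 presynaptic genes Nrxn2 rose by 0.88 and 3 fell (1 and 2 adjusted over the list alone), among them Syt1 (log2 fold change -0.25) and Erc2 (-0.22). With the trend removed 1 rose and 6 fell (2 and 6 adjusted over the list alone), and the fry adjusted p went from 0.928 to 0.000944, while camera did not pass (adjusted p = 0.0562; adjusted p = 0.207 with an estimated correlation). The fold changes of this comparison rose with GC content: their median was -0.17 in the lowest of 5 equal groups of genes by GC content and 0.31 in the highest.

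Clock genes changed both ways: of 21 measured, 10 rose and 4 fell (12 and 4 adjusted over the list alone). Per2 rose from 3.37 ± 0.217 to 9.10 ± 0.393 FPKM (log2 fold change 1.21, SE 0.07, limma adjusted p = 0.000681), Nfil3 by 1.28 and Bhlhe40 by 0.73, while Dbp had a log2 fold change of -0.64. Among translation factors 4 of 28 rose and 5 fell (6 and 6 adjusted over the list alone), with Eif5 at -0.42. Of 27 nuclear genes of oxidative phosphorylation 2 rose and 5 fell (2 and 5 adjusted over the list alone), Cox6c at 0.27 and Ndufs1 at -0.36. In the Gsk3 and Akt signalling list none of 15 rose and 2 fell (0 and 2 adjusted over the list alone; median 0.07), and with the trend removed 1 rose and 3 fell, with a median of -0.0276. The counts higher and lower with the trend removed were 27 and 1 in the immediate early list, 20 and 0 in the chaperone list, 27 and 2 in the ribosomal protein list, 6 and 3 in the clock list, 3 and 1 among translation factors and 2 and 5 in oxidative phosphorylation. None of 24 interferon-response genes and none of 15 mitochondrially encoded genes passed with limma, over all genes or adjusted over the list alone; their medians were -0.19 and 0.05. Fxr1 itself had a log2 fold change of 0.03 (limma adjusted p = 0.758) and Fmr1 of -0.15 (limma adjusted p = 0.173). Fxr2 rose by 0.27 (limma adjusted p = 0.0257), and had a log2 fold change of -0.06 (limma adjusted p = 0.424) with the trend with GC content and length removed.

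Markers of single cell types moved little as sets. Of 15 astrocyte markers 3 rose and 2 fell (5 and 2 adjusted over the list alone), with Gjb6 at 1.12 and Glul at 0.47. Of 15 oligodendrocyte markers 2 rose and 2 fell (2 and 2 adjusted over the list alone), with Mbp at 0.92, Opalin at -0.86 and Aspa at -0.64. Excitatory neuron markers had 4 of 15 higher and 3 lower (4 and 3 adjusted over the list alone), Slc30a3 at 0.55 and Rorb at -0.35, and inhibitory neuron markers 3 of 14 higher and none lower (2 and 0 adjusted over the list alone), Vip at 0.42. Endothelial and mural markers had 1 of 10 higher and 2 lower (1 and 4 adjusted over the list alone), with Kdr at -0.37. The microglia, oligodendrocyte precursor and meninges or choroid lists each had 1 member higher, of 15, 6 and 6 (1, 1 and 0 adjusted over the list alone), the striatal list had 1 of 9 higher and 1 lower (0 and 0), and none of 5 blood genes passed. After removal of the trend, the counts higher and lower were 3 and 2 for astrocyte, 1 and 2 for oligodendrocyte, 2 and 3 for excitatory, 1 and 1 for inhibitory, 0 and 2 for endothelial and 0 and 2 for striatal markers. They were 1 and 0 for microglia, 0 and 1 for precursor and 0 and 0 for meninges or choroid markers.

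Outside the lists, the largest falls among passing genes with a proper symbol were in Rac1 (ENSMUSG00000001847, chromosome 5, 143503634 to 143528036), from 68.1 ± 0.328 to 18.8 ± 0.612 FPKM (log2 fold change -1.80, SE 0.05, limma adjusted p = 2.95e-05), Stard7 (-1.57) and Rnf146 (-1.56). The Rac1 change lay in a single transcript, ENSMUST00000080537, at 65.7 ± 0.536 FPKM in sleep and 18.0 ± 0.225 in enforced wake. Zbed6, Hnrnpdl, Tipin and Haus1 followed with -1.21, -1.16, -1.07 and -0.98. Rpph1, the RNA subunit of ribonuclease P, rose by 1.89. Protein-coding genes took 90.4% to 92.0% of total FPKM in sleep and 85.3% to 86.3% in enforced wake, so non-coding RNA as a whole took more. Whether Rpph1 was bound to ribosomes was not tested.

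**Figure D2:**
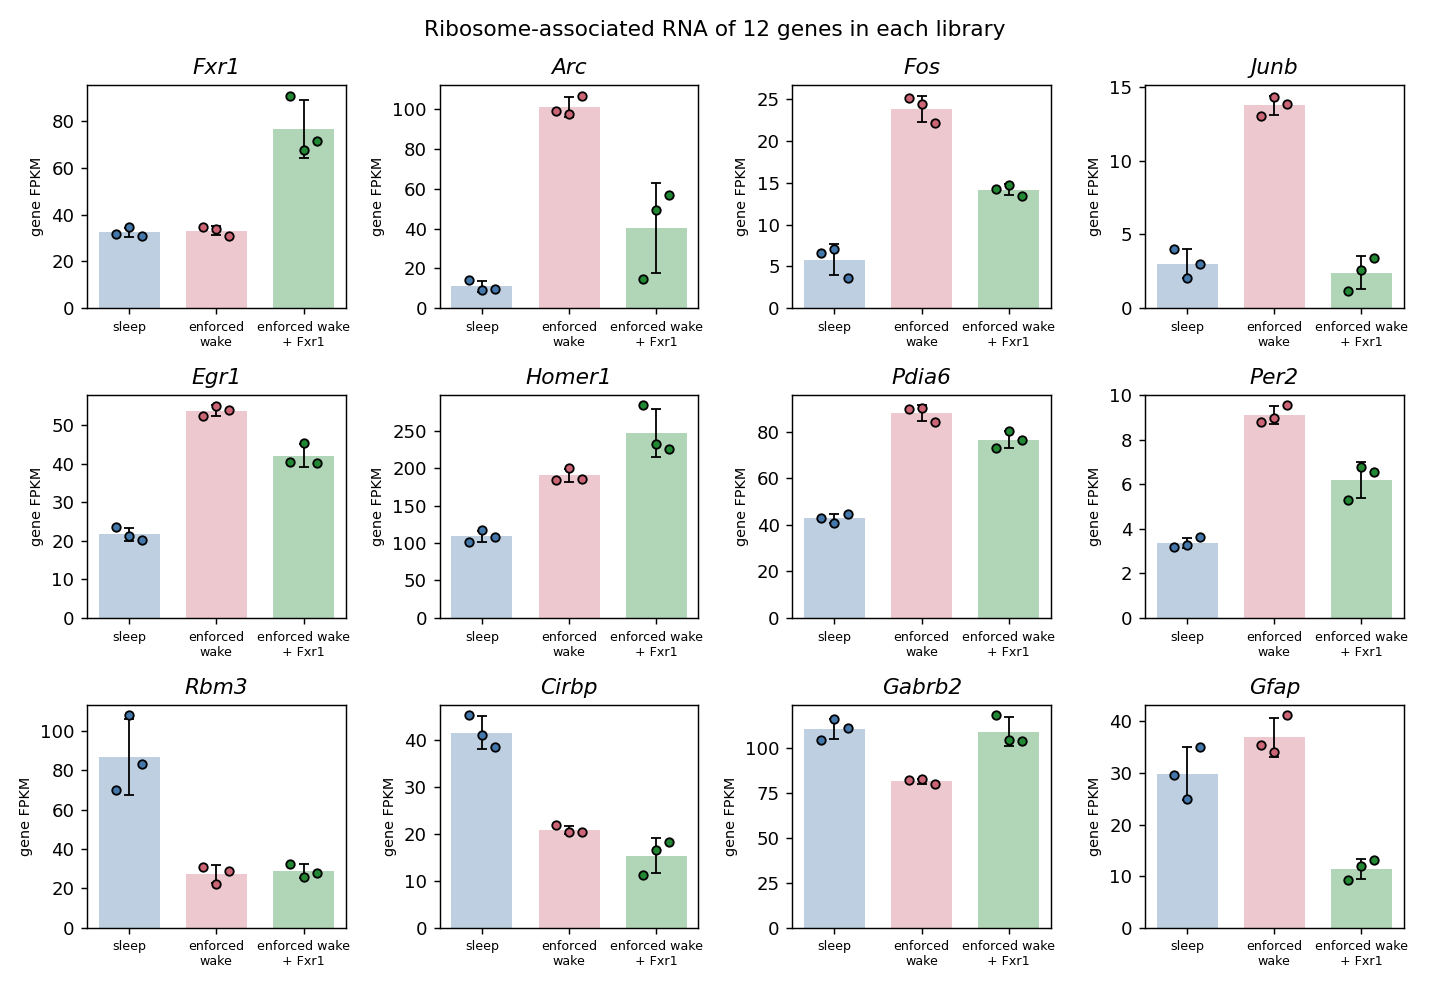
FPKM of 12 genes in each of the 9 libraries (points), with the group mean (bar) and SD (error bar, n = 3), for sleep, enforced wake and enforced wake with Fxr1. Arc lies at 10.9 ± 2.72 FPKM in sleep, 101.2 ± 5.01 in enforced wake and 40.4 ± 22.5 with Fxr1, and Fxr1 at 32.5 ± 2.03, 33.3 ± 1.97 and 76.9 ± 12.5.

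Over all genes, 4156 of 14673 passed a limma adjusted p of 0.05 in enforced wake against sleep, 2298 higher and 1858 lower, and 909 of them differed by at least 1.5-fold. The groups did not overlap in 49.5% of genes, and in 45.0% with the trend with GC content and length removed, where chance gives 10%. Genes share the deviations of their library, so this distance does not measure how many genes differ. With the trend with GC content and length removed, 3386 genes passed, 1526 higher and 1860 lower, and 2292 genes passed in the same direction in both fits. For single transcripts 1055 of 29116 passed, 596 higher and 459 lower. The gene count fell to 2570, 1822 and 1866 without enforced wake replicate 1, 2 or 3. The transcript count fell to 568, 611 and 322 without sleep replicate 1, 2 or 3 and to 320, 289 and 256 without enforced wake replicate 1, 2 or 3.

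The comparison of enforced wake with and without Fxr1 overexpression asked which ribosome-associated RNAs differ when Fxr1 is raised. Besides Fxr1 itself, few single genes passed. Junb, a component of the AP-1 transcription factor (ENSMUSG00000052837, chromosome 8, 84974484 to 84978718), fell from 13.7 ± 0.669 FPKM in enforced wake control to 2.39 ± 1.11 with Fxr1 (n = 3 each), by 2.18 on the log2(FPKM + 1) scale (SE 0.25, limma adjusted p = 0.0375), and Fos from 23.9 ± 1.56 to 14.2 ± 0.676 FPKM (log2 fold change -0.71, SE 0.09, limma adjusted p = 0.0443). Gfap, the astrocyte intermediate filament (ENSMUSG00000020932, chromosome 11, 102887336 to 102900912), fell from 36.9 ± 3.76 to 11.4 ± 1.96 FPKM (log2 fold change -1.62, SE 0.14, limma adjusted p = 0.0245). Rac1 was higher, at 68.0 ± 1.97 FPKM against 18.8 ± 0.612 (log2 fold change 1.80, SE 0.08, limma adjusted p = 0.00109), close to its level of 68.1 ± 0.328 in sleep. The Rac1 change again lay in transcript ENSMUST00000080537, at 18.0 ± 0.225 FPKM in enforced wake control and 66.1 ± 1.34 with Fxr1. The step may come from the transcript estimates, which was not tested. Fmr1 and Fxr2, the other members of the family, had log2 fold changes of 0.43 and -0.55 and did not pass over all genes (limma adjusted p = 0.0895 and 0.0880), while 2 of the 3 members, Fxr1 included, were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.218; adjusted p = 0.810 with an estimated correlation). With the trend with GC content and length removed only 1 was higher and none lower on that adjustment, and the median went from 0.43 to 0.15.

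Of 34 immediate early genes 2 fell and none rose over all genes, and 20 fell and 2 rose adjusted over the list alone, with a median of -0.46 (camera adjusted p = 0.000846; adjusted p = 0.810 with an estimated correlation). The fry adjusted p was 0.0143 for this list. Arc had 40.4 ± 22.5 FPKM against 101.2 ± 5.01 and did not pass over all genes (limma adjusted p = 0.0925), with 14.8, 49.5 and 56.8 FPKM in the 3 Fxr1 libraries. Homer1 had 247 ± 31.9 FPKM against 190 ± 8.75 and did not pass either (limma adjusted p = 0.0912). With the trend with GC content and length removed, the median of the immediate early list was -0.05, 6 fell adjusted over the list alone, camera still passed (adjusted p = 0.00370; adjusted p = 0.5847 with an estimated correlation) and fry did not (adjusted p = 0.104). Fos no longer passed (limma adjusted p = 0.103), while Junb had a log2 fold change of -1.31 (limma adjusted p = 0.00642).

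Of 52 ribosomal protein genes 1 fell, Rplp1, from 166 ± 13.3 to 74.4 ± 11.8 FPKM (log2 fold change -1.16, limma adjusted p = 0.0409), and none rose; 26 fell adjusted over the list alone. The median of the list was -0.43 (camera adjusted p = 2.3e-05, and 0.810 with an estimated correlation). It was -0.30 with the trend removed (3 higher and 24 lower adjusted over the list alone), where Rplp1 itself had -0.34 and no longer passed (limma adjusted p = 0.157). The list did not pass with fry (adjusted p = 0.0758, and 0.132 with the trend removed). Of 15 astrocyte markers only Gfap passed, and 6 fell adjusted over the list alone, with a median of -0.34 (camera adjusted p = 0.00317; adjusted p = 0.810 with an estimated correlation) and of -0.44 with the trend removed (8 lower adjusted over the list alone). Aldoc had 50.03 ± 5.48 FPKM against 87.8 ± 9.19 and Fgfr3 3.27 ± 0.524 against 7.92 ± 1.66, and neither passed over all genes (limma adjusted p = 0.0592 for both). Among 15 microglia markers Trem2 fell, from 1.17 ± 0.0338 to 0.170 ± 0.0529 FPKM (log2 fold change -0.89, limma adjusted p = 0.0245), and 5 fell adjusted over the list alone (median -0.30; camera adjusted p = 0.0517); with the trend removed 1 fell adjusted over the list alone, with a median of -0.0834. None of 14 oligodendrocyte markers passed over all genes (2 higher and 4 lower adjusted over the list alone, 0 and 1 with the trend removed; median 0.03).

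The GABA receptor list lay higher with Fxr1 as a set, with a median of 0.33 (camera adjusted p = 0.000846; adjusted p = 0.810 with an estimated correlation), and of 0.14 with the trend removed. None of its 15 genes passed over all genes; 8 rose adjusted over the list alone, and 1 with the trend removed. Gabrb2 had 109 ± 8.05 FPKM against 81.5 ± 1.49. The 15 mitochondrially encoded genes had a median of 0.60 (camera adjusted p = 0.000846; adjusted p = 0.810 with an estimated correlation), none passing singly or adjusted over the list alone, and the set call was lost with the trend removed (camera adjusted p = 0.287). Among 29 chaperones Hspa1a, a stress-inducible heat shock protein, fell by 0.78 (limma adjusted p = 0.0366), with 7 lower adjusted over the list alone; with the trend removed none was, the median went from -0.19 to -0.0357, and Hspa1a had a log2 fold change of -0.05. No gene of the postsynaptic density list passed over all genes with limma, and 6 of 31 were higher and 14 lower adjusted over the list alone (median -0.56; with the trend removed 0 and 0, median -0.05). The clock, glutamate receptor, presynaptic, translation factor, oxidative phosphorylation and Gsk3 and Akt lists held no gene passing over all genes and had camera adjusted p of 0.218, 0.601, 0.601, 0.631, 0.654 and 0.947. Adjusted over the list alone, 1 of 21 clock genes was higher and 8 lower, 4 of 28 glutamate receptor genes were higher and 5 lower, 1 presynaptic gene was lower, and none passed in the other three. After removal of the trend these counts were 0 and 0 for the clock list, 2 and 2 for glutamate receptors, 0 and 0 for the presynaptic list, and 2 and 1 for the Gsk3 and Akt list. No gene of the excitatory, inhibitory, striatal, precursor, endothelial, blood, meninges or interferon lists passed over all genes with limma either. Adjusted over the list alone, 4 of 5 blood genes fell (median -0.88; -0.20 and none passing with the trend removed), 2 of 14 inhibitory markers fell, 2 of 6 meninges or choroid genes fell, 1 of 5 precursor genes fell, and 1 excitatory marker rose and 1 fell. With the trend removed 3 inhibitory markers rose and none of the others in these lists passed.

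Outside the lists, the non-coding gene AY036118 rose most among passing genes with a proper symbol. It went from 22.7 ± 8.19 FPKM to 371, 1472 and 531 in the 3 Fxr1 libraries (log2 fold change 4.88, limma adjusted p = 0.0366). AY036118 is annotated as a long intergenic non-coding RNA (chromosome 17, 39847113 to 39848035). Whether this RNA was bound to ribosomes or carried over into the total RNA libraries was not tested. Rnf146 rose by 1.73, with its transcript ENSMUST00000162335 at 0.00297 FPKM in enforced wake and 18.2 with Fxr1, the nicotinic receptor subunit gene Chrnb2 by 1.33, Rpe by 0.99, Pcmtd1 by 0.83 and Klhdc10 by 0.76. Among passing genes with a proper symbol, the lowest log2 fold changes were those of Cbarp (-2.45), the histone H4 genes Hist1h4b (-2.21) and Hist1h4a (-2.04), Lingo1 (-1.90), the muscarinic receptor Chrm1 (-1.83), Ccdc85b (-1.75) and Ydjc (-1.68). Genes of the histone H4 family are near-identical copies, so reads could be split between them and their single values are uncertain. With the trend with GC content and length removed, Lingo1 and Pcmtd1 no longer passed (limma adjusted p = 0.116 and 0.0966).

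**Figure D3:**
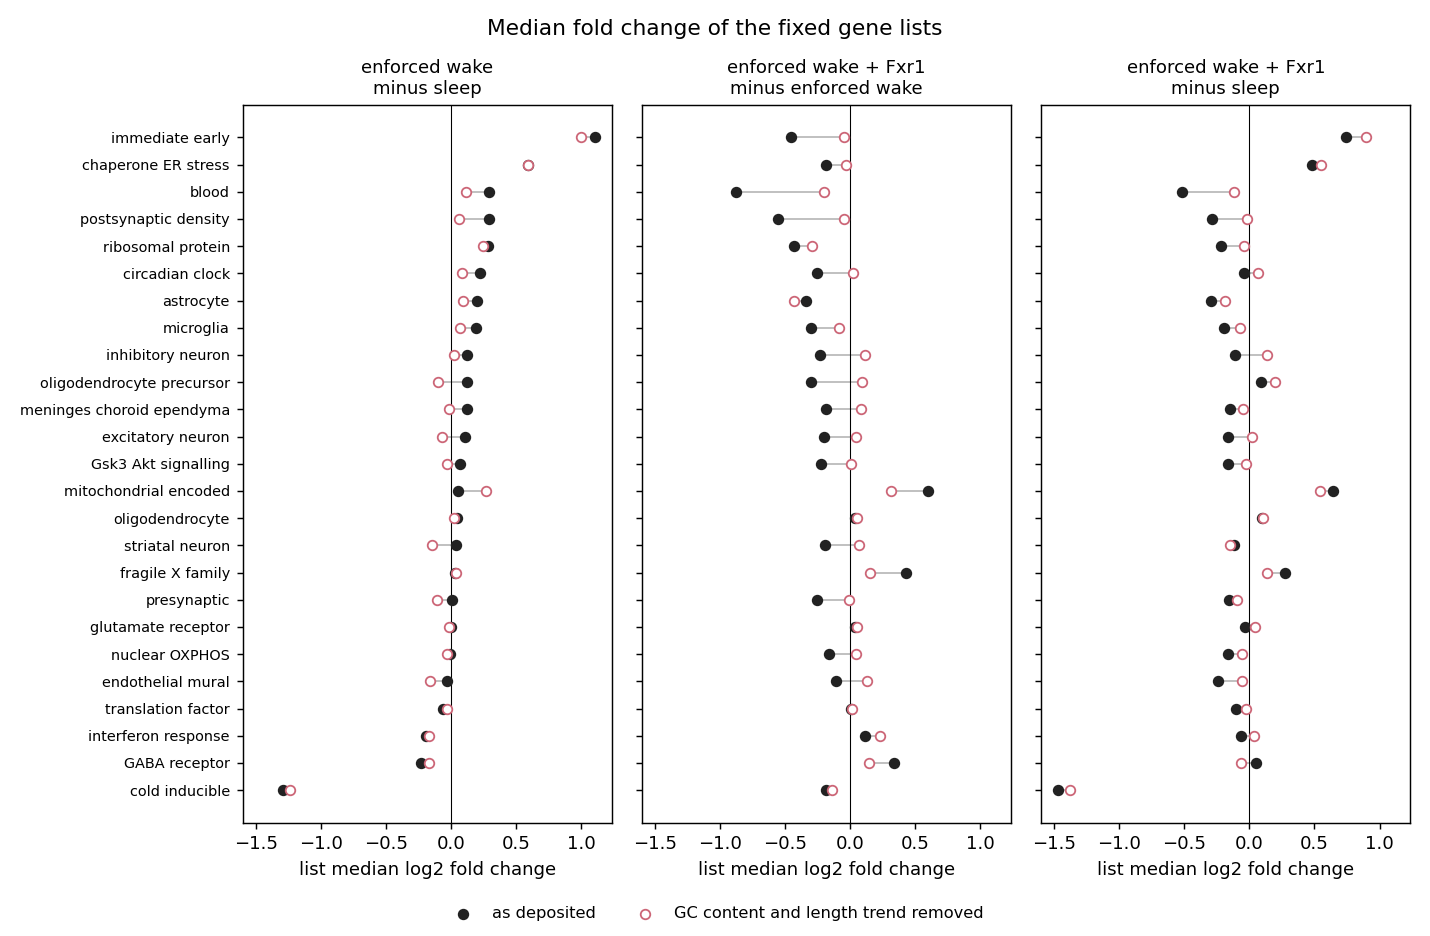
Median log2 fold change of the 25 fixed gene lists (vertical axis) in the 3 comparisons, from log2(FPKM + 1) values as deposited (filled) and with the trend with GC content and length removed (open). The immediate early list lies at 1.11 and 1.0 in enforced wake against sleep, and at -0.46 and -0.05 in enforced wake with Fxr1 against enforced wake.

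Over all genes, 60 of 14563 passed with limma, 12 higher and 48 lower, and 5582 had an unadjusted p under 0.05; the groups did not overlap in 52.5% of genes, where chance gives 10%. The fold changes fell with GC content, with a median of 0.30 in the lowest of 5 equal groups of genes by GC content and -0.65 in the highest. With that trend removed 46 genes passed, 18 higher and 28 lower, and 28 genes passed in the same direction in both fits. After that removal 3289 genes had an unadjusted limma p under 0.05, and the groups did not overlap in 34.2% of genes. Genes of a library share its deviations, so the distance from 10% does not measure how many genes differ. For transcripts 258 of 28837 passed, 82 higher and 176 lower. Quantile normalization moved the median of all genes from -0.06 to 0.07. The gene count was 3316 without Fxr1 replicate 1 (828 higher and 2488 lower), 4 without Fxr1 replicate 2, and 4, 2 and 2 without enforced wake replicate 1, 2 or 3; the transcript count was 787 without Fxr1 replicate 1 and 167 without enforced wake replicate 2. In simulated data of the same spread, with independent genes, 63% of genes changed by 2-fold and 19% of those changed by 1.5-fold were called.

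Whether genes that differed with enforced wake moved the other way with Fxr1 was asked across the 14383 genes tested in both comparisons. Of the 48 genes lower with Fxr1, 26 had risen with enforced wake, among them Junb, Fos, Hspa1a and Rplp1, where independent lists of these sizes would share 7.66. Of the 12 genes higher with Fxr1, 5 had fallen with enforced wake, among them Rac1, Rnf146, Klhdc10 and Pcmtd1, where independent lists would share 1.52. The steps in Rac1 and Rnf146 may come from the transcript estimates, which was not tested. No gene rose in both (1.92 for independent lists) and 1 fell in both (6.06), Psmf1. After removal of the trend with GC content and length, 16 genes lower with Fxr1 had risen with enforced wake (2.97 for independent lists), 8 higher had fallen (2.25), and 1 rose and 1 fell in both. Of the genes named here, Fos, Hspa1a, Rplp1 and Pcmtd1 no longer passed with Fxr1 after that removal. The log2 fold changes of the 2 comparisons correlated across genes with r = -0.67. Both comparisons use the same 3 enforced wake libraries, and unchanged groups simulated against them gave a median r of -0.50 (-0.57 to -0.42 over 100 simulations). Shared calls numbered 0 in 20 such simulations, which says nothing about the shared controls, since unchanged groups gave at most 0 and 1 calls in the 2 comparisons. With the trend with GC content and length removed r was -0.54, inside the simulated range of -0.60 to -0.41, and 67.4% of genes had opposite signs beside a simulated 66.7%. The covariance was -0.107, beside a simulated -0.0207, and with the trend removed it was -0.0527 beside -0.0155. The 3 control libraries cannot be split into parts of at least 2 each, so part of the excess may come from the shared controls. The simulation drew each gene independently, so its range leaves out variation that genes share.

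The comparison of enforced wake with Fxr1 against sleep in GFP controls asked which differences from sleep were seen when wake and Fxr1 overexpression were combined. Of 33 immediate early genes 18 rose and 2 fell (22 and 2 adjusted over the list alone), with a median log2 fold change of 0.74 (camera adjusted p = 2.7e-17; adjusted p = 0.0942 with an estimated correlation). Fos rose from 5.80 ± 1.87 FPKM in sleep to 14.2 ± 0.676 (n = 3 each), by 1.20 on the log2(FPKM + 1) scale (SE 0.19, limma adjusted p = 0.0117), and Egr2, Ptgs2, Inhba and the neurotrophin gene Bdnf rose by 1.69, 1.60, 1.39 and 1.26. Junb had 2.39 ± 1.11 FPKM against 3.02 ± 0.991 and Arc 40.4 ± 22.5 against 10.9 ± 2.72, and neither passed (limma adjusted p = 0.487 and 0.0559); Btg2 was one of the 2 that fell, by 0.43. Of 28 chaperones 12 rose and none fell (18 and 0 adjusted over the list alone; camera adjusted p = 2.8e-14; adjusted p = 0.0942 with an estimated correlation), with Sdf2l1 at 1.0, Pdia4 at 0.83 and Pdia6 at 0.83. With the trend with GC content and length removed 20 of the 28 chaperones rose, and 23 immediate early genes rose and 2 fell. Rbm3 fell by 1.55 (SE 0.18) and Cirbp by 1.40 (SE 0.16), at limma adjusted p of 0.00342 or less (camera adjusted p of the list 0.00698; adjusted p = 0.141 with an estimated correlation).

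Clock genes again moved both ways, 5 of 21 higher and 3 lower (6 and 4 adjusted over the list alone), with Nfil3 at 1.0, Per2 at 0.71, Dbp at -1.33 and Ciart at -0.68. In the postsynaptic density list 3 of 31 rose and none fell (3 and 0 adjusted over the list alone). Homer1 rose from 109 ± 7.41 to 247 ± 31.9 FPKM (log2 fold change 1.17, SE 0.10, limma adjusted p = 0.00144), Lrrtm2 by 0.43 and Dlg1 by 0.38. The Homer1 transcript ENSMUST00000080127 went from a mean of 75.7 to 97.9 FPKM, so most of the Homer1 rise again lay in its other transcripts. Among 15 astrocyte markers 1 rose and 2 fell (1 and 5 adjusted over the list alone): Gjb6 rose by 0.91, and Gfap and Sox9 had log2 fold changes of -1.31 and -0.51. The 15 mitochondrially encoded genes had a median of 0.64 (camera adjusted p = 5.6e-06; adjusted p = 0.928 with an estimated correlation), and none passed singly or adjusted over the list alone. In the lists with few calls, Fxr1 (1.21, limma adjusted p = 0.00190) was the only passing member of its family of 3, Pik3r1 (0.35) 1 of 2 genes higher in the Gsk3 and Akt list, Vip (0.70) the only inhibitory marker, and Grm3 (-0.54), Eif4ebp1 (-0.70), Emx1 (-0.83) and Opalin (-0.86) fell in the glutamate receptor, translation factor, excitatory neuron and oligodendrocyte lists. Emx1 and Sox9 no longer passed with the trend with GC content and length removed (limma adjusted p = 0.0936 and 0.0573). None of 52 ribosomal protein genes and none of 15 GABA receptor genes passed with limma, over all genes or adjusted over the list alone; their medians were -0.22 and 0.05. The counts higher and lower over all genes with the trend removed were 2 and 0 for ribosomal proteins, 0 and 1 for GABA receptors, 6 and 4 for clock genes, 3 and 1 for the postsynaptic density, 1 and 4 for astrocyte markers and 1 and 0 for mitochondrially encoded genes.

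Outside the lists, AY036118 had the largest rise among named genes (4.94), followed by Rasd1 (1.52), the splicing factor Luc7l (1.44), Cbln4 (1.38) and Timp1 (1.31). Adnp (-1.79), Psmf1 (-1.56), Trex1 (-1.32) and Lrrc61 (-1.30) fell. Trex1 no longer passed with the trend removed (limma adjusted p = 0.0599). In all 1153 of 14562 genes passed with limma, 476 higher and 677 lower, 426 of them by at least 1.5-fold, and 237 of 28447 transcripts. The groups did not overlap in 32.7% of genes, and in 33.6% with the trend with GC content and length removed, where chance gives 10%. The median fold change of all genes was -0.09, and fold changes fell with GC content, from a median of 0.12 in the lowest of the 5 groups to -0.36 in the highest. The split of the calls moved with the scaling: 675 higher and 427 lower with size factors, 660 and 370 with quantile normalization, and 1056 and 817 with the trend with GC content and length removed. The count fell to 252, 347 and 256 without sleep replicate 1, 2 or 3 and to 552, 470 and 643 without enforced wake replicate 1, 2 or 3, and it was 183 with only the 2 groups compared in the fit.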

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

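The correction for GC content and length, the leave-out and block fits with it, and the alternatives for the third comparison were chosen after seeing the data. So was quantile normalization for the tests of the gene lists. The other settings were fixed before. Where a value moved, the cause was not tested unless a setting's own construction gives it. Depth, an estimated 2.99e7 to 3.74e7 fragments, limits mainly transcripts and genes of low FPKM. In simulated data with independent genes 19% of 1.5-fold changes were called for Fxr1 against enforced wake control and 67% for enforced wake against sleep.

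Gene calls in enforced wake against sleep (4156) kept within 1.5 times of that count under pseudocount 0.1, both filters, size factors, quantile normalization, the robust fit, the replicate block and the GC correction. They were 1411 with all 9 libraries in 1 fit, where the spread of the Fxr1 libraries enters, 2154 with the replicate block and GC correction, 1073 at an adjusted p under 0.01, 909 with a fold of at least 1.5 and 15 from the authors' p-values combined per gene. Transcript calls (1055) were 346 with no filter, 505 with the robust fit, 11 with the replicate block, 449 with all 9 libraries, 2765 and 110 at adjusted p under 0.1 and 0.01, 701 with a fold of at least 1.5 and 14 by the authors' q-values. Leaving out 1 library gave 1822 to 3631 genes (1519 to 2397 with the GC correction, with 1734, 1934, 2085 and 2215 between) and 256 to 611 transcripts.

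Gene calls in enforced wake with Fxr1 against enforced wake control (60) were 29 with pseudocount 0.1, 4 with no filter, 34 with a mean FPKM of at least 2, 92 with quantile normalization, 1 with the replicate block, 1 with the block and GC correction, 3360 with all 9 libraries in 1 fit, 3727 and 3 at adjusted p under 0.1 and 0.01, and 14 from the authors' p-values. Transcript calls (258) were 158 with no filter, 153 with a mean FPKM of at least 2, 0 with the replicate block, 397 and 92 at adjusted p under 0.1 and 0.01, and 24 by the authors' q-values. Leaving out 1 library gave 2 to 3316 genes (4 to 312 with the GC correction, with 33 and 35 between) and 167 to 787 transcripts. The step from 60 to 3727 calls between the thresholds shows that many genes lay just above 0.05.

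Gene calls in enforced wake with Fxr1 against sleep (1153) were 372 with the replicate block, 1873 with the GC correction, 183 with only the 2 groups in the fit, 2405 and 196 at adjusted p under 0.1 and 0.01 and 426 with a fold of at least 1.5; leaving out 1 library gave 252 to 1443 (872 to 1655 with the GC correction). The list calls with camera numbered 6, 5 and 4 in the 3 comparisons and 0, 0 and 0 with an estimated correlation; leaving out 1 library gave 6 to 7, 4 to 7 and 4 to 6. The Fxr1 log2 fold change of 1.17 had an adjusted p of 0.0931 with the replicate block (1.17), and lay between 1.05 and 1.26 with 1 library left out. It passed in transcripts ENSMUST00000001620 and ENSMUST00000197694 and not in ENSMUST00000198051 (0.48), ENSMUST00000200392 (0.97) or ENSMUST00000197853 (1.03). The correlation of -0.67 between the fold changes was -0.76 over genes with an unadjusted p under 0.05 in enforced wake against sleep, -0.54 with the GC correction, and -0.69 to -0.57 with 1 library left out.

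No label says whether the replicate numbers pair the libraries. Same-numbered deviations correlated at -0.0772, 0.0479 and 0.0974 between sleep and enforced wake, beside -0.144 to 0.0986 for different numbers. Between enforced wake and Fxr1 they correlated at 0.148, -0.0136 and 0.225, beside -0.211 to 0.0989 for different numbers. So few values cannot settle whether the numbers pair the libraries. What a call lost with the block means is therefore left open. Of the single genes named, Fxr2 turned in enforced wake against sleep, with -0.0591 after the GC correction (limma adjusted p = 0.424). Of the other values of named genes and lists under all settings, 4836 and 877 were the same, 142 and 20 stronger, 412 and 3 weaker. A change of sign was counted as the same where neither fit passed. This was so for several lists, among them the Gsk3 and Akt list in enforced wake against sleep, with a median of 0.0692, and of -0.0276 after the GC correction. The excitatory neuron list went from 0.109 to -0.0664 in that comparison. In enforced wake with Fxr1 against enforced wake control the inhibitory neuron list went from -0.231 to 0.114. The count of same values therefore does not mean that the direction of such lists held.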

Other observations

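The 6 gene lists of the next paragraphs, the tests of GC content in the first pattern, of Fxr1 library 1, of non-neuronal RNA and of other splits were chosen after the results were seen; the tests of shared controls and GC content in the second pattern and the ratio of gene totals to transcripts in the third were set down before their results, and the share made up by other transcripts after. Because the 6 lists were chosen from the results, their p-values are descriptions and test nothing.

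Glucocorticoid-responsive genes were higher in enforced wake than in sleep. Of 13 such genes 11 rose and none fell, with a median log2 fold change of 0.92 on the log2(FPKM + 1) scale (n = 3 per group; camera adjusted p = 9.0e-08 over the 6 lists; adjusted p = 0.0927 with an estimated correlation), and with the trend with GC content and length removed 10 rose, with a median of 0.85 (adjusted p = 0.0225 with an estimated correlation). Among genes named after their values were seen, Fkbp5, a co-chaperone of steroid receptors, rose by 1.29 (SE 0.07, limma adjusted p = 0.000451), Plin4 by 1.14, Sult1a1 by 1.12, Cdkn1a by 1.24, and the metallothionein genes Mt1 and Mt2 by 1.18 and 1.58. In enforced wake with Fxr1 against sleep 5 of 12 rose, among them Fkbp5 (1.14), Sult1a1 (1.12) and Cdkn1a (0.81), with a median of 0.40 (adjusted p = 0.0317 with an estimated correlation); with the trend removed 9 rose (adjusted p = 0.0180 with an estimated correlation). Mt1 fell by 1.11 with Fxr1 against enforced wake (limma adjusted p = 0.0366). Among 10 phosphatases of MAP kinases 4 rose in enforced wake (camera adjusted p = 0.00295; adjusted p = 0.174 with an estimated correlation), including Dusp4 (1.44), Dusp5 (1.39) and Dusp6 (0.89), and these 3 were also higher with Fxr1 against sleep (1.17, 0.99 and 0.86). With the trend removed 4 phosphatases rose and 1 fell in enforced wake, and 4 rose with Fxr1 against sleep (adjusted p = 0.195 and 0.108 with an estimated correlation). Dusp5 and Dusp6 also belong to the immediate early list.

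All 13 measured histone H4 genes rose in enforced wake, with a median of 1.32 (camera adjusted p = 1.4e-09; adjusted p = 0.174 with an estimated correlation), and 30 of 42 other histone genes rose and 1 fell, with a median of 0.64. All 13 H4 genes also rose with the trend removed (median 0.90), but of the others 15 rose and 3 fell (median 0.24). With Fxr1 against enforced wake 4 of the 13 H4 genes and 3 of 40 others fell, with medians of -2.06 and -0.92 (camera adjusted p of the H4 list 2.3e-08; adjusted p = 0.186 with an estimated correlation). Only 4 H4 genes and none of the others fell with the trend removed, with medians of -1.19 and -0.18, so most of the change of the other histones followed the trend. With Fxr1 against sleep none of 12 H4 genes passed (median -0.77), and 2 of 35 others rose and 5 fell (median -0.38). The camera adjusted p of the H4 list was 0.00553 there, and 0.467 with an estimated correlation. With the trend removed these medians were -0.337 and -0.0480. Most messages of these histones lack a poly(A) tail, and they were measured in total RNA libraries. Of 15 genes of the cholesterol synthesis list 4 fell in enforced wake, among them Insig1 (-0.58), Idi1 (-0.41) and Hmgcs1 (-0.35) (camera adjusted p = 0.0411; adjusted p = 0.174 with an estimated correlation). With Fxr1 against sleep 3 of the 15 fell, among them Insig1 at -0.41 (camera adjusted p = 0.00975; adjusted p = 0.0636 with an estimated correlation). Splicing factors of the SR family and related kinases had 4 of 14 higher and 1 lower in enforced wake (camera adjusted p = 0.197), with Srsf10 at 0.85, Srsf7 at 0.59 and Srsf5 at -0.87. With Fxr1 against sleep 2 were higher and 1 lower (camera adjusted p = 0.000320; adjusted p = 0.0636 with an estimated correlation), with Srsf10 at 1.13 and Srsf5 at -0.81. With the trend removed 5 cholesterol genes fell in enforced wake, and 6 fell and 1 rose with Fxr1 against sleep (adjusted p = 0.140 and 0.0284 with an estimated correlation). For the splicing list 5 were higher and 1 lower in enforced wake (camera adjusted p = 0.000357; adjusted p = 0.0523 with an estimated correlation), and 4 and 1 with Fxr1 against sleep (adjusted p = 0.0284 with an estimated correlation).

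The first pattern is the fall of fold changes with GC content in enforced wake with Fxr1 against enforced wake, where GC content and length accounted for 62.2% of the variance of the fold changes over all genes, so library composition is a candidate explanation for most of the small changes; a real shift of GC-rich messages cannot be told apart from it, because the trend differs between the groups. Over the 60 called genes the corrected change was a median of 0.624 of the uncorrected one (interval 0.486 to 0.717), which leaves open how much of their change follows the trend. Without Fxr1 library 1 the uncorrected changes kept a median of 0.950 of their size (0.928 to 0.967). All 60 were among the 3316 genes that passed in the fit without it. The 60 genes were chosen by a fit that held every Fxr1 library, and in all of them the groups did not overlap. A gene moved by library 1 alone could hardly be among them, so these values do not test that library as the source. The immediate early list went from -0.46 to -0.0494 (-0.263 to -0.00612) with the trend removed, which leaves the trend open for most of it. The ribosomal list kept -0.297 (-0.369 to -0.194) and the astrocyte list -0.435 (-0.490 to -0.104) with it removed. These intervals were drawn over list members, which share the same 3 libraries per group. Camera at the preset correlation passed there (adjusted p = 6.6e-08 for the ribosomal and 2.2e-07 for the astrocyte list). It did not pass with an estimated correlation. The fry adjusted p was 0.132 for the ribosomal and 0.104 for the astrocyte list with the trend removed. Whether the trend is the whole cause of these 2 changes is therefore left open. A lower share of all non-neuronal RNA would lower oligodendrocyte markers too. The astrocyte median minus theirs was -0.489 (-0.684 to -0.162) with the trend removed. The microglia, blood, precursor, meninges and endothelial medians were -0.30, -0.88, -0.30, -0.185 and -0.112 as deposited. They were -0.0834, -0.203, 0.0936, 0.0795 and 0.128 with the trend removed. The interval was drawn over list members, and a single cell type cannot stand for the others, so a lower share of such RNA is left open. A change within astrocytes, or in how much of their RNA was pulled down, may remain too.

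The second pattern is that fold changes with Fxr1 ran opposite to those with enforced wake, which the design ties to Fxr1 as an untested biological explanation. Independent variation of genes in the shared enforced wake libraries gave a lowest simulated covariance of -0.0280, against -0.107 observed. With the trend with GC content and length removed the observed value was -0.0527 against a lowest simulated one of -0.0227. By covariance, such independent variation did not reach the observed values, with or without the trend. The corrected correlation of -0.54 lay inside its simulated range of -0.60 to -0.41. The simulations treat genes as independent, so they cannot produce a deviation that many genes of the 3 enforced wake libraries share. Such a deviation would also give opposite fold changes, so the shared controls are left open as a source. Among protein-coding genes with the trend removed, the correlation was -0.48 beside a simulated -0.50, and 66.5% of genes had opposite signs beside a simulated 66.6%, while the covariance of -0.0360 lay beyond a lowest simulated -0.0142. A reversal by Fxr1 remains an untested hypothesis.

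The third pattern is that 25 transcripts were at 0.01 FPKM or less in all libraries of one group and at 5 or more in all of the other between Fxr1 and enforced wake; 24 of them lay in genes with several transcripts. The change of the gene totals was a median of 0.157 of that of the transcripts (0.103 to 0.190), but many of these transcripts are a small part of their gene, and the ratio would be 0.302 (0.129 to 0.407) had no reads moved between transcripts. Other transcripts made up a median of 0.507 of the change (0.194 to 0.702) over 23 genes, so moved reads and a real change of the transcripts cannot be told apart. For 5 of the 25 the ratio was above 0.25: Ly6h (totals of 32.1 FPKM in enforced wake and 7.16 with Fxr1), Rnf146, Rundc3a, Hdac5 and RP23-358K1.5, which are named after their values were seen. Similar jumps reached gene totals within a group: Stard7 had 64.5, 18.9 and 51.4 FPKM in the 3 Fxr1 libraries and 18.7 to 19.97 in the 3 enforced wake libraries, so the steps in Rac1, with 65.7 to 69.4 FPKM in the sleep and Fxr1 libraries and 18.4 to 19.5 in enforced wake, and in Rnf146, both counted among the shared calls, may come from the transcript estimates too, which was not tested.

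With 3 libraries per group there are 10 splits of 6 libraries, so no share of splits under 0.05 can be had; in each case 1 split, the real one, gave a result as large. In enforced wake against sleep the real split called 4156 genes and 1055 transcripts, and the highest other split 7 and 29. In enforced wake with Fxr1 against enforced wake control these were 60 genes and 258 transcripts against 1 and 22, and 25 on-or-off transcripts against 7. In enforced wake with Fxr1 against sleep they were 1153 genes against 6. Every other split mixes the groups, so any difference between the groups, technical or not, raises the spread within its parts and lowers its calls. The counts of the other splits are therefore no chance level, and no conclusion is drawn from the contrast.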
